A study of Mus musculus with 6 samples.

How the data were processed

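RNA from sorted leukaemia cells was measured on 6 Affymetrix mouse transcriptome arrays, 3 control and 3 Dnmt3b-KO. The leukaemia was induced by MLL-AF9, a fusion oncogene. Per the labels' protocols, cells were taken from the bone marrow of recipient mice at the end stage of disease, sorted by flow cytometry, and total RNA was extracted and biotin-labelled. The markers used for sorting, and the sex of donors and recipients, were not given in the sources used here. The deposited values are on a log2 scale. The authors' normalization was RMA, per the submitters' processing notes, with no version given. Deposited values reach 19.59, above 16, the log2 of the scanner's 16-bit range, so a further step that is not stated stretched or shifted the scale. Differences are given in log2 units as deposited and are not converted to folds.

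The deposited table holds 72688 rows, of which 6732 are array controls. A probe table with older annotation named 30604 rows with exactly 1 gene symbol and 2146 with several, and 33206 rows had no name there. Rows with several symbols were not named. Symbols of 813 rows were brought up to date through the gene identifier. For each gene the row with the highest mean was kept, which left 30141 genes. Chromosome and gene order came from a reference table of assembly GRCm38.p6 for 29836 genes. The build behind the array rows was not settled, so no coordinates are given. Some rows hold identical values on all arrays: the 30141 genes have 29819 distinct sets of values.

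Dnmt3b-KO was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment over all genes, threshold 0.05). Lists of genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over 31 lists that cover pathways, sample handling and other cell types. Chromosomes were tested in the same way. Groups, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule names Dnmt3b, then up to 10 genes per direction with the largest change among genes past the threshold whose group values do not overlap and whose higher group mean exceeds the median gene. Open places go to genes that meet the same conditions of level and overlap, with a change of at least 1 and the smallest unadjusted p, named as not passing. Each list adds up to 2 members per direction past the threshold, or else the member with the smallest p. Genes with clone names were passed over.

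A comparison without Dnmt3b-KO replicate 3 is reported beside the planned one. Leaving out each array in turn was planned, but reading this one as a comparison of its own, with the rule for named genes and the alternatives repeated on it, was chosen after seeing the data. Counting genes with identical values once was also chosen after seeing the data. The other alternatives were a variance trend with robust fitting, array weights, the replicate number as a block, repeated quantile normalization, centring, removal of dim genes, the mean of probe sets, probe sets tested singly, other thresholds and a test without empirical Bayes.

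The fits were tested on simulated data with the real gene means and spreads and 200 changed genes among 30141. With 5 arrays, 49.3% of changes of 0.5, 86.6% of changes of 1 and 97.0% of changes of 2 log2 units were recovered. With 6 arrays and the measured deviation of Dnmt3b-KO replicate 3 added, the shares were 10.4%, 61.2% and 84.8%. The changed genes were drawn at random from all genes, whatever the deviation of that array for them. Among the real genes, 293 changed by at least 1 over 6 arrays and 0 were called. These shares therefore do not tell what part of the real changes the 6-array fit would call. The number of arrays limits the precision. The labels do not say whether each array is a separate mouse, so p-values measure the spread between these samples, which may be technical. Figures were drawn with matplotlib.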

Results

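Gene expression was measured in mouse acute myeloid leukaemia cells driven by MLL-AF9, a fusion oncogene, on 3 control arrays and 3 Dnmt3b-KO arrays. Dnmt3b encodes a DNA methyltransferase that places new methyl groups on DNA. The comparison asks which genes differ between the Dnmt3b-KO and control arrays. Array medians over 30141 genes ran from 4.75 to 4.85 on the log2 scale.

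The targeted gene, Dnmt3b, measured 6.79 ± 0.04 (SD, n = 3) in control, and 6.47, 6.63 and 5.96 in Dnmt3b-KO replicates 1, 2 and 3. The difference of -0.44 ± 0.17 (SE) did not pass the threshold (limma, adjusted p = 0.78), although all 3 Dnmt3b-KO values lay below the controls. The row covers the whole transcript, and which exons were deleted is not given in the sources used here, so this level checks the labels only weakly.

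One array stood apart. Dnmt3b-KO replicate 3 correlated with the other 5 at 0.981 to 0.982 across genes, against 0.998 to 0.999 among those 5, and the first principal component, with 81.3% of the variance, separated it from them. It carried transcripts of the Y chromosome that the others lacked. Eif2s3y measured 8.26 against 4.48 ± 0.06 (SD, n = 5), Uty 7.98 against 4.16 ± 0.04 and Kdm5d 6.88 against 3.97 ± 0.05. Xist, the RNA that silences an X chromosome in female cells, was present on all 6 arrays, at 15.44 on this one and at 16.70 ± 0.05 on the others. Compared with Dnmt3b-KO replicates 1 and 2, 1215 genes were higher by more than 1 and 885 lower by more than 1, whereas replicates 1 and 2 differed from each other by that much in 3 and 4 genes. Gpnmb, a glycoprotein of macrophages, measured 16.16 there and at most 5.55 on the other 5 arrays, Dab2 13.43 and at most 4.92, and Rasgrp3 11.94 and at most 3.67. The lower values lie near or below the median gene, so the size and order of these differences are not given. Of 25 measured monocyte and macrophage genes, 14 were higher by more than 1, among them Mrc1, Ctss, Csf1r and Lyz2, and 2, F13a1 (-1.86) and Ccr2 (-1.04), were lower by more than 1. Apoe differed by 0.05. Genes lower on this array included Cpa3 by -2.87, Angpt1 by -2.26 and Tespa1 by -2.37.

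**Figure D1:**
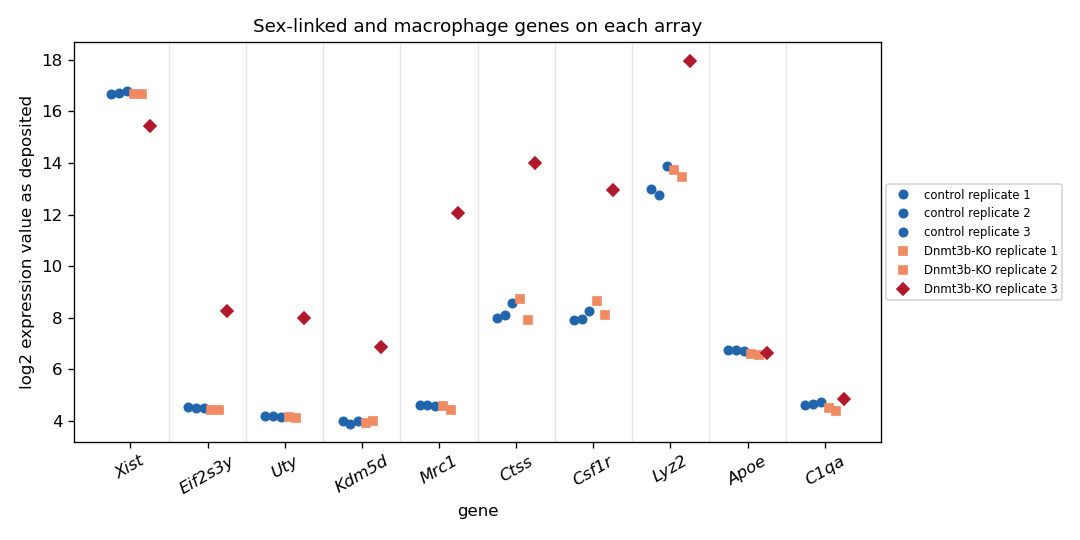
Log2 expression values as deposited (vertical axis) of sex-linked and macrophage genes (horizontal axis) on each of the 6 arrays, 1 point per array. Dnmt3b-KO replicate 3 lies above the other arrays for Eif2s3y, Uty, Kdm5d, Mrc1, Ctss, Csf1r and Lyz2, below them for Xist, and close to them for Apoe.

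Over all 6 arrays, the genes with the smallest p that filled the places of the rule included the eosinophil granule genes Prg2 and Epx, with changes of -3.90 ± 0.48 (SE) and -2.17 ± 0.15. On the higher side were the transcription factor gene Klf6, at 2.04 ± 0.34, and Anxa1, which encodes an annexin, at 2.00 ± 0.28. None of these passed the threshold. Cpa3, at -4.08 ± 0.82, had a greater spread. Across 30141 genes limma called 0, with a smallest adjusted p of 0.185. There were 16 genes at an adjusted p under 0.25, 14 of them lower, and 1920 at an unadjusted p under 0.05. The groups did not overlap for 14.9% of genes, where chance gives 10%. Further genes named as not passing were Trf, Lair1, Arrdc3, Klf2, Cd300lb, Slfn2, Ptafr and Siglece on the higher side, with changes of 1.03 to 1.92. On the lower side they were Kcnq5, Ear-ps2, Hba-ps4, Ear-ps9, Eml5, Ttll3, Plekhh2 and Pbx3, with changes of -1.94 to -1.01. Epx, Ear-ps2 and Ear-ps9 measured near or below the median gene in Dnmt3b-KO, so the size of their changes is not exact.

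Of the 31 gene lists, 9 were called over 6 arrays by camera with the preset correlation, 2 higher and 7 lower. The split was 3 higher and 6 lower after repeated quantile normalization and 5 higher and 7 lower with arrays centred on the median. It turned to 6 higher and 5 lower among genes above the median level, and was 5 and 6 above the 40th percentile. None was called with the directional test of fry, and 0 with an estimated correlation, where adjusted p = 0.67 for each of the 9. The mixed test of fry counts changes in either direction. It called mast cell, basophil and eosinophil markers (adjusted p = 0.011) and erythroid markers (0.029). It also called immediate early and heat shock genes (0.029) and apoptosis regulators (0.034). Members of every list passed the threshold over all genes 0 times. On the lower side were erythroid markers (adjusted p = 0.00030), S phase and G2/M phase genes (both 0.00054), the MLL-AF9 and HOX programme (0.00065), mast cell, basophil and eosinophil markers (0.00085), primary granule genes (0.0011) and MYC and ribosome biogenesis genes (0.023). On the higher side were NF-kB and inflammatory cytokine genes (0.00090) and monocyte and macrophage genes (0.023). Dnmt3b-KO replicate 3 differed from replicates 1 and 2 in the same direction for several of these, with list medians of 1.42 for monocyte and macrophage genes, 1.02 for NF-kB genes, -0.98 for primary granule genes, -0.74 for the HOX programme, -0.73 for G2/M and -0.52 for S phase genes. Without that array, none of the lists with these medians was called by camera (adjusted p from 0.20 to 0.92). Over 6 arrays and adjusted over the list alone, 4 members of the HOX programme, 6 of the mast cell list and 5 of the erythroid list were lower. In the erythroid list 1 member, Tfrc, was higher. Of immediate early and heat shock genes, a list for sample handling, 4 were higher and 1 lower, of late granulocyte genes 1 higher and 2 lower, and of apoptosis regulators 1 higher and 1 lower. The other 22 lists, among them DNA methylation machinery and germline genes silenced by DNA methylation, had adjusted p from 0.063 to 0.90. Median, mean and test differed in sign for glycolysis genes, B cell markers and stromal markers. None of 20 chromosomes was called, and the 100 genes beside Dnmt3b had a median change of 0.0067 and were not called by limma's camera.

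Leaving out Dnmt3b-KO replicate 3 gave 509 genes past the threshold, 283 higher and 226 lower. Leaving out any other array gave 0. Of these 509, 48 share 1 set of values with the small nuclear RNA Rnu6. The 509 hold 454 distinct sets, and counting repeated values once gave 394 genes, 250 higher and 144 lower. Array weights over all 6 arrays called 103 genes, but gave Dnmt3b-KO replicate 3 a weight of 0.11 against 1.26 to 2.17 for the others, so this fit is close to leaving that array out. Dnmt3b-KO replicate 3 lay on the same side of the control mean as the other 2 Dnmt3b-KO arrays for 43.6% of the 509. That share counts each of the 48 genes with the Rnu6 values. Over all genes the share was 53.6%. As a set, the 509 calls describe Dnmt3b-KO replicates 1 and 2. Replicate 3 has a deviation of its own in many genes, so its side cannot show whether the calls hold beyond those arrays. Most named genes with the largest changes, among them Prg2, Cd24a, Trf and Klf6, lay beyond every control on replicate 3 too, in the same direction. Mef2c, Tctex1d1, Muc13 and F7 did not. Replicate 3 differed from replicates 1 and 2 by -1.63 for Prg2, -1.51 for Cd24a and 1.05 for Klf6, further in the same direction. For Trf it differed by -0.84, against the rise. The deviation of that array thus enters these values, and they are no separate support. The comparison without Dnmt3b-KO replicate 3 was singled out after the data were seen. It also rests on few arrays: leaving out 1 more gave 13 (without Dnmt3b-KO replicate 1), 30 (without replicate 2), 43, 264 and 97 genes (without control replicate 1, 2 and 3). Without control replicate 2 the balance turned to 104 higher and 160 lower, and without Dnmt3b-KO replicate 1 to 6 higher and 7 lower. A test without empirical Bayes gave 0.

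Without that array, 6 of 18 mast cell, basophil and eosinophil markers fell, 1, Siglecf, rose by 1.01 ± 0.13 (SE), and 11 did not pass. Prg2 fell by 3.36 ± 0.19 (SE; adjusted p = 0.0039), Cpa3, a mast cell carboxypeptidase, by 3.12 ± 0.21 (0.0047), Epx, eosinophil peroxidase, by 2.01 ± 0.07 (0.00087) and Hdc, which makes histamine, by 1.71 ± 0.25 (0.035). All 4 were lower still on Dnmt3b-KO replicate 3, where Siglecf measured 10.25, below every control. That array was lower than replicates 1 and 2 by more than 1 in 885 genes, so a further fall there is not particular to these 4. Adjusted over the list alone 7 were lower and 2 higher. The list was called (adjusted p = 0.0055), though not with an estimated correlation (adjusted p = 0.85) or with directional fry (adjusted p = 0.066). Mixed fry called it (adjusted p = 0.0015), but without that array mixed fry called most lists, among them imprinted genes (0.0017). The median change of the mast cell, basophil and eosinophil list was -0.02 and its mean -0.57.

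Zc3h12c, which encodes a CCCH zinc finger protein, fell from 9.50 ± 0.06 in control to 5.04 and 5.40 (adjusted p = 0.00034); it measured 7.63 on Dnmt3b-KO replicate 3. Cd24a, Kcnq5, Cyp2a4, Mef2c and Eml5 fell by 1.57 to 1.95. Mef2c, a transcription factor gene of the MLL-AF9 programme, measured 10.73 on Dnmt3b-KO replicate 3, above the control mean of 9.81. Tdrd9, a germline helicase, rose from 5.34 ± 0.05 in control to 7.59 and 7.87. Zc3h12c and Epx in Dnmt3b-KO and Tdrd9 in control measured near the median gene, so the size and order of these changes are not exact. Trf, transferrin, rose by 2.20 ± 0.07, and Tctex1d1, Muc13, Arrdc3, Klf2, Anxa1, Klf6, F7 and Krt80 by 1.66 to 1.84. Tctex1d1, Muc13 and F7 were within 0.2 of the control mean on Dnmt3b-KO replicate 3.

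**Figure D2:**
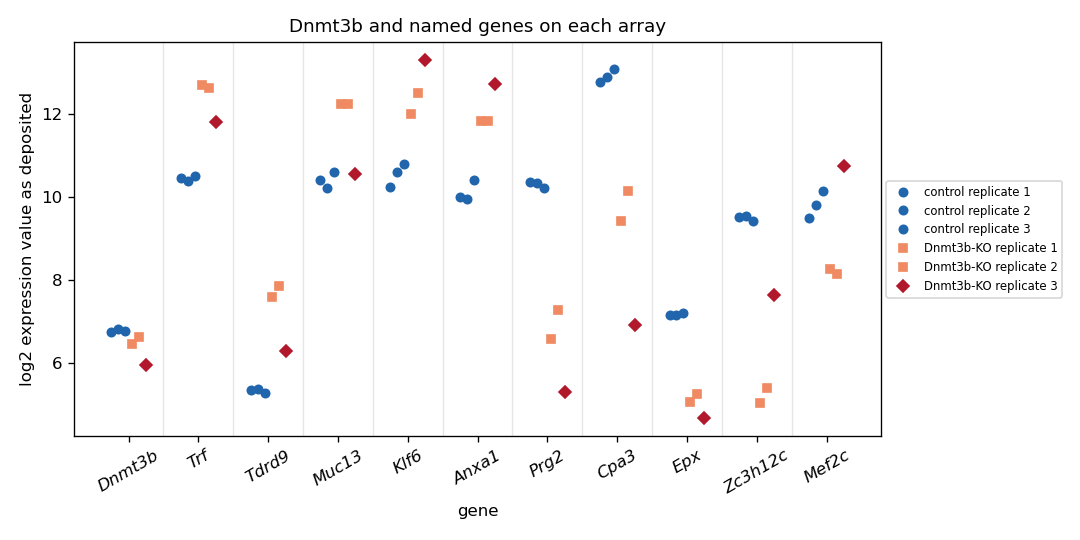
Log2 expression values as deposited (vertical axis) of Dnmt3b and 10 of the named genes (horizontal axis) on each of the 6 arrays, 1 point per array. Trf, Klf6 and Anxa1 are higher and Prg2, Cpa3, Epx and Zc3h12c lower on all 3 Dnmt3b-KO arrays than in control, whereas Mef2c on Dnmt3b-KO replicate 3 lies above the control mean.

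In the MLL-AF9 and HOX programme, Cdk6 rose by 0.70 and Meis1 by 0.65 while Pbx3 fell by 0.88 and Mef2c by 1.60. On Dnmt3b-KO replicate 3, Cdk6 at 16.18, Meis1 at 10.21 and Pbx3 at 6.96 lay below every control, and Mef2c lay above every control. The other 14 of 18 members did not pass, and the list was not called (adjusted p = 0.78). Adjusted over that list alone 3 were higher and 6 lower. Of 17 stem cell genes 14 did not pass, while Cd34 fell by 1.01, Angpt1 by 0.89 and Gata2 by 0.48; adjusted over the list alone 3 were lower and 2 higher. That list was not called (adjusted p = 0.29) and had a median change of -0.02. Of 22 late granulocyte genes 4 rose, among them Anxa1 and Trem3 (0.52), and 1, Retnlg, fell to a level below the median gene; adjusted over the list alone 7 were higher and 3 lower. Of 20 CDK inhibitors and p53 targets 18 did not pass, while Pmaip1 rose by 0.60 and Trp53inp1 by 0.47; adjusted over the list alone 4 were higher and 1 lower. Of the genes for sample handling Hsph1 fell by 1.06 (adjusted p = 0.039), and adjusted over that list alone 7 were higher and 3 lower. These 3 lists were not called (adjusted p = 0.20 for each). Of 16 hypoxia genes, the other list for sample quality, 2 rose, Bnip3l by 0.46 and Pdk1, also a glycolysis gene, by 0.33. Of 20 apoptosis regulators 1, Bcl2, fell by 0.95; adjusted over the list alone 5 were higher and 3 lower. Single members of other lists that were not called passed as well: Ly6c2 (-0.38) and Aurka (-0.33) fell, and Itgb3 (0.72) and Ifih1 (0.52) rose. On Dnmt3b-KO replicate 3, Itgb3, Ifih1, Trem3 and Pmaip1 lay below every control, against their rise. Ly6c2, Aurka and Bcl2 also lay below every control there, and Trp53inp1 and Pdk1 above every control. Hsph1 at 10.13 and Bnip3l at 10.03 lay within the control values there. Of 22 MYC and ribosome biogenesis genes 19 had changes below 0 and 2 passed, Dkc1 (-0.43) and Nop16 (-0.35), with the list called (adjusted p = 0.00012; adjusted p = 0.85 with an estimated correlation). On Dnmt3b-KO replicate 3 Dkc1 at 12.98 lay below every control, but Nop16 at 9.13 lay above every control, against its fall. Of 10 MHC class I genes 9 had changes above 0 and 0 passed singly, with the list called on the higher side (adjusted p = 0.0012; 0.85 with an estimated correlation). Over all 6 arrays 5 MHC class I genes had changes above 0 and 5 below, and the list was not called (camera, adjusted p = 0.11). Erythroid markers were called on the lower side (adjusted p = 0.0012; 0.85 with an estimated correlation) with 0 of 14 members past the threshold and 5 lower and 1 higher when adjusted over the list alone. The other 27 lists had adjusted p from 0.16 to 0.97. Median, mean and test differed in sign for primary granule, germline, adhesion, megakaryocyte, dendritic cell and stromal genes. Dnmt3b itself differed by -0.24 ± 0.07 (adjusted p = 0.16).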

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

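The test in this part was chosen after the data were seen. Rows without a single gene name were not used in the gene comparison. Without Dnmt3b-KO replicate 3, and with rows of identical values counted once, 151 of 34600 such rows were higher and 41 lower than in control (limma). They are listed because no other comparison used these values. Their number does not stand out: named genes counted once gave 250 higher and 144 lower of 29819 over the same arrays. The unnamed rows were not rerun with 1 more array left out or without empirical Bayes. Counting every unnamed row instead of distinct ones gave 366 higher and 64 lower, with 284 distinct sets of values among the 430. Over all 6 arrays the same rows counted once gave 0 calls, with 1954 at an unadjusted p under 0.05. Counting every row gave 12 higher and 1 lower over 6 arrays, but those 13 hold 2 distinct sets of values and the calls end when repeats are counted once.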

How the results depend on the processing

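The alternatives on 5 arrays, and counting repeated values once, were chosen after the data were seen. Over 6 arrays the count of genes was 0 under every alternative run except array weights (103; 60 higher, 43 lower) and leaving out Dnmt3b-KO replicate 3, with a leave-one-out range of 0 to 509. Dnmt3b stayed below control and short of the threshold throughout. The count of lists, 9, became 0 with an estimated correlation and 0 with directional fry, with a leave-one-out range of 4 to 11. Its split of 2 higher and 7 lower became 3 and 6 after repeated quantile normalization, 5 and 7 with arrays centred, 6 and 5 among genes above the median level, and 5 and 6 above the 40th percentile. The 0 called chromosomes stayed 0. With the replicate number as a block the counts were 0 genes, 9 lists and 0 chromosomes. Same-numbered samples had correlated deviations of 0.13, 0.03 and 0.11. For each control array the same-numbered Dnmt3b-KO array correlated highest, yet both Dnmt3b-KO replicates 1 and 2 deviated most alike with control replicate 1. The Dnmt3b-KO deviations were taken from a mean that includes replicate 3, so they cannot settle whether the numbers mark pairs. The main fit took no pairs.

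Without Dnmt3b-KO replicate 3, the 509 genes became 1003 among genes above the median level, 842 above the 40th percentile, 1148 at an adjusted p under 0.1, 66 with a change of at least 1, 0 in a test without empirical Bayes, 0 with all 6 arrays and 103 with all 6 arrays and array weights. The filters test fewer genes. The lists were rerun with a variance trend only, since camera takes no robust option. The cause of the other differences was not tested. Leaving out 1 more array gave 13 to 264 genes, where a lone Dnmt3b-KO array is assumed to vary like the controls. The 4 lists became 0 with an estimated correlation, 0 with directional fry, and 4 to 7 with 1 more array left out. Counting repeated values once gave 394 genes. Over 6 arrays no gene passed the threshold. Over 5 arrays no named gene that passed changed sign. For the genes with the largest changes this was fixed when an array was left out, because they were chosen for groups that do not overlap. Single named genes over 5 arrays lost the threshold in 125 of the leave-one-out values and in 47 of the others, 40 of these in the test without empirical Bayes. These 40 are every named gene that had passed, as that test called 0 genes. Another 159 leave-one-out values stayed the same, which includes named genes that had not passed, and 1 gained the threshold.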

Other observations

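All tests in this part were chosen after the results were seen. Tdrd9, Dmc1 and Stag3, which act in meiosis, were higher on Dnmt3b-KO replicates 1 and 2 than in control, by 2.39, 1.40 and 1.35, where the controls of Tdrd9 and Stag3 lay near the median gene. Dmc1 and Stag3 lie outside the rule for named genes and were picked after their values were seen. On Dnmt3b-KO replicate 3 Dmc1 measured 9.68, below the control mean of 9.84, whereas Tdrd9 at 6.29 and Stag3 at 5.37 lay above every control. A general rise of meiosis genes was tested as a hypothesis on 29 other meiosis genes. Of these, 22 lay below the median gene and decide nothing. The 7 above it had a median change of 0.13, 5 above 0 and 2 below, from 0.30 for Prdm9 to -0.15 for Syce2, and 0 passed the threshold. Whether other meiosis genes moved to a lesser degree stays open.

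Dnmt3b-KO replicate 3 stood apart from the other 5 arrays. A leukaemia from a male donor alone is argued against by Xist, which lay 10.58 above the median gene. RNA of male cells beside that of female cells is a candidate explanation: the Y-linked genes were higher and Xist differed by -1.27. Monocytic differentiation alone is argued against by the Y-linked genes, higher by 2.91 to 3.82 with a median of 3.78, but may add to the pattern. Whether macrophages brought the RNA stays open: their list was higher by a median of 1.42 and Lyz2 measured 17.97, yet Apoe was nearly level and F13a1 and Ccr2 were lower. The markers of the sort are not given in the sources used here.

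Prg2, Cpa3, Epx and Hdc were lower on Dnmt3b-KO replicates 1 and 2, while 11 of the 18 markers in their list did not pass and no member passed over 6 arrays. Neither mature mast cells nor eosinophils in the control samples can be told apart from a change in the leukaemia cells. The mast cell proteases Tpsab1, Tpsb2, Cma1 and Mcpt4 (median change -0.011) and the eosinophil genes Il5ra and Ccr3 all lay below the median gene, where a change cannot be read. The eosinophil markers above it went apart: Siglecf was higher by 1.01 and Prg3 lower by 0.61. Because Siglecf and Prg3 went apart, these markers decide nothing. On Dnmt3b-KO replicate 3 Siglecf measured 10.25, below every control. That array was lower than replicates 1 and 2 by more than 1 in 885 genes, so this value is not particular to Siglecf. Ms4a2, a receptor gene of mast cells, was lower by 0.90. Prg3 and Ms4a2 were picked after their values were seen. An effect of the genotype on the leukaemia cells stays open and was not tested further.

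Zc3h12c was lower by far more than its surroundings. Among the 10 measured genes on each side, the 8 expressed ones had a median change of -0.046, which argues against a change of the whole segment. A change that reaches its nearest neighbours on one side may remain: the 3 nearest there had a median of -0.35, and 1 of them, Fdx1, fell by 0.79. An effect of the genotype was not tested apart from this.

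Other splits of the arrays are too few for a share under 0.05. Over 6 arrays the real split called 0 genes and the highest of the other splits 0. With a real count of 0, all 10 of 10 splits must give as many, so this comparison decides nothing. Over 5 arrays the real split called 509 and the highest other 0, so 1 of 10 splits gave as many.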
